A study of Homo sapiens with 6 samples.

How the data were processed

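HK-2 is an immortalised line of human renal proximal tubular epithelial cells, the cells that line the first part of the kidney tubule and take back most of what is filtered. Per the labels, cells were grown in a serum-free keratinocyte medium with pituitary extract and EGF, seeded a day before the start of treatment and exposed at near confluence. The series holds 6 RNA-seq libraries from total RNA: 3 of untreated cells and 3 of cells exposed for 24 h to phosphoramidon, an inhibitor of zinc metallopeptidases such as neprilysin and endothelin-converting enzyme. The labels give no dose, and they do not say whether libraries selected poly(A) RNA or kept strand. The titles of the untreated libraries also carry the letters CSE, which the labels do not explain. They were taken as untreated from the treatment label, and every comparison rests on that. Nothing says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

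The deposited values are FPKM per gene for 38126 Ensembl gene IDs in each library, as found from the values. They are not whole, and multiplied by gene length they fall on whole multiples of 1 step per library. The submitters' processing notes name CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0, DESeq2 1.22.1 and the build GRCh38, with no role or order. The annotation release, the use of strand and whether reads or read pairs were counted are not given in the sources used here. Fragments in this text stand for either. Of 34623 genes above 0 in any library, 99.9% gave whole fragments within 0.05 at some length, and 79.2% did so at the merged exon length of GENCODE 29. For the rest, a length was searched that gave whole fragments, so the higher share is no check on those lengths. The step gives assigned totals of 23493829, 24308789 and 24815378 fragments in untreated replicates 1 to 3 and 18690099, 24919568 and 19563640 in phosphoramidon replicates 1 to 3. One fragment on a gene of 1 kb was thus worth 0.0401 to 0.0535 FPKM, which sets the precision of low values. Names came from a gene name table, which matched 37892 of the IDs, and coordinates from GENCODE 29 (GRCh38).

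The plan made before the data were examined assumed a count table and a count-based test. The files hold FPKM, and limma 3.58.1 (R 4.3.3) was used on log2(FPKM + 0.1) in place of that test. The planned test was not run on the recovered fragments either, although voom was, as an alternative. The pseudocount and the filter on low genes, which stands in for the planned one, were set once the unit was known, and the design, threshold, lists and rule for named genes were kept. Values were first divided by TMM factors (30% of M values and 5% of A values trimmed) computed from the recovered fragments. Genes with at least 10 recovered fragments in at least 3 libraries were tested, 16174 in all. The model held the group alone, with a trended and robust variance prior, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A second test (limma's treat) asked whether the change exceeded 1.5-fold. A fold change is on the log2(FPKM + 0.1) scale and understates the change of low genes, while FPKM means and SDs are the deposited values.

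In all, 44 gene lists were fixed before the data were examined. The 43 with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, and adjusted over lists. A correlation estimated from each list and the self-contained test fry were alternatives. Library measures were compared by exact permutation, which cannot go below 0.1 with 3 against 3. Genes are named by a rule fixed in advance: M13 metallopeptidases with a mean of at least 10 fragments, the 10 highest and 10 lowest fold changes among called genes with a symbol, a mean of at least 50 fragments and no overlap between groups, and the lowest p-values among called members of lists that passed or had at least 3 called members (up to 4 in the first 6 lists, up to 2 in the others). The rule takes 109 genes, and the results of some of these and of some other list members are not reported here. Genes named beyond it were chosen after their values were seen.

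The procedure was tested on simulated data: in 5 simulations on 15994 genes each, fragments were drawn from the untreated means and the real library sizes with 200 genes changed. The fit recovered 19.8% of genes changed by 1.25-fold, 64.2% at 1.5-fold, 86.7% at 2-fold and 98.8% at 4-fold, and called 0.0685% of unchanged genes. On the same draws voom recovered 45.9%, 77.5%, 92.9% and 100%, and called 0.0596% of unchanged genes. The fit used was thus the less sensitive of the pair in these simulations. A list of genes moved together by 1.25-fold was called in 5 of 5 simulations and a list left alone in 0. These calls used camera p below 0.05 without adjustment. Genes were drawn independently with the same dispersion, so the simulated lists held no correlation between members. The real ribosomal protein list had an estimated correlation of 0.39. The simulations thus do not show how often camera calls unchanged lists whose members are correlated. Besides the moved list, only 200 genes were changed in each simulation, whereas 5431 of 16174 tested genes were called in the data. The adjusted threshold depends on the share of changed genes, so the simulated recovery and error rates need not hold for these data. Within each group, every pair of libraries differed by more than counting noise (chi-square per degree of freedom 3.22 to 7.51), so none was taken for a copy of another, which does not show that they are separate cultures. Alternatives covered voom, RLE and upper-quartile factors, no scaling, other filters and pseudocounts, removal of the trend on GC content and length, thinning to equal depth, the replicate number as a block and leaving out each library. Figures were drawn with matplotlib 3.10.9.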

Results

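Gene expression was measured by RNA-seq in HK-2 cells, an immortalised human proximal tubular epithelial line, untreated per the treatment label (n = 3) or exposed to phosphoramidon for 24 h (n = 3). Per library, 18714053 to 24950223 fragments were recovered from the FPKM values, summed over genes. Every sum lay slightly above the total given by the step (23521765 against 23493829 in untreated replicate 1), so some recovered numbers cannot be exact. Library measures numbered 7, each tested by exact permutation, and the lowest of their Benjamini-Hochberg adjusted p-values was 0.233. Neither the total (24233807 ± 666806 against 21083360 ± 3377049, SD, n = 3, exact permutation p = 0.4, adjusted p = 0.56) nor the number of genes with at least 10 fragments (16070.0 ± 206 against 16003 ± 469.8, exact permutation p = 0.9, adjusted p = 0.9) separated the groups. The share of fragments on ribosomal protein genes was 3.27 ± 0.0325% in untreated and 2.62 ± 0.0884% in phosphoramidon libraries, and the 10 highest genes took 12.1 ± 0.614% against 10.3 ± 0.188%. Both had an exact permutation p of 0.1, the smallest that 3 against 3 allows, and so had replication-dependent histones (0.00949 ± 0.000236% against 0.00875 ± 0.000429%), with adjusted p = 0.233 for each of the 3. Mitochondrially encoded mRNAs took 5.94 ± 0.781% against 6.65 ± 0.103% (exact permutation p = 0.2, adjusted p = 0.35), and the number of genes above 0 did not separate the groups (exact permutation p = 0.8, adjusted p = 0.9). The first principal component held 55.8% of the variance and separated the groups.

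The design asks which genes changed after 24 h of phosphoramidon. In the mitosis list 35 of 40 genes rose, while 70 of 72 ribosomal protein genes, 31 of 40 genes of ATF4 and amino acid supply, 24 of 34 matrix genes and 17 of 29 tubular injury genes fell. All 5 lists passed camera at the preset correlation, but with an estimated correlation only the mitosis list did (adjusted p = 0.02, against adjusted p = 0.27 for the others). Of the protein-coding genes named by the rule, the lowest fold change was that of SLC2A2, which encodes the glucose transporter GLUT2 (ENSG00000163581, chromosome 3, 170996348 to 171026750 on GRCh38), which fell from 39.4 ± 0.793 to 7.32 ± 0.656 FPKM (SD, n = 3 in each group here and below). The secreted collagenase MMP1 fell from 10.9 ± 0.624 to 2.74 ± 0.282 FPKM, and DHRS2, a short-chain dehydrogenase, rose from 0.155 ± 0.0391 to 1.46 ± 0.173 FPKM. In all, 5431 of 16174 tested genes (33.6%) passed limma's test at adjusted p below 0.05, 2529 higher and 2902 lower. The counts of called members in each list are to be read beside this share. Most changes were small, with a median size of 0.37 on the log2 scale. The test against 1.5-fold left 130 genes, of which 24 were higher and 106 lower (13 higher without phosphoramidon replicate 2, and 68 lower without untreated replicate 2). Both splits depend on scaling: in the values as deposited, without factors between libraries, 3647 genes were higher and 2169 lower, 38 and 87 of them past 1.5-fold by that test, and the median of all tested genes moved from 0.01 to 0.07. The count past 1.5-fold was 273 with voom and 68 with a pseudocount of 1. The groups did not overlap in 7768 genes (48.0%), where chance gives 10%.

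The M13 metallopeptidases include the enzymes phosphoramidon inhibits, and 3 of them were expressed enough to test. ECE1, endothelin-converting enzyme 1 (ENSG00000117298, chromosome 1, 21217247 to 21345572), rose from 15.8 ± 1.45 to 24.2 ± 0.0965 FPKM, a log2 fold change of 0.55 ± 0.07 (SE) with limma adjusted p = 4.2e-04. MME, neprilysin (ENSG00000196549, chromosome 3, 155024124 to 155183729), was near the threshold, at 1.58 ± 0.0816 to 1.31 ± 0.101 FPKM (log2 fold change -0.32 ± 0.10 (SE), adjusted p = 0.037). PHEX, a phosphate-regulating endopeptidase (ENSG00000102174, chromosome X, 22032441 to 22251310), was nearer to it, at 0.824 ± 0.114 to 1.17 ± 0.108 FPKM (log2 fold change 0.40 ± 0.13 (SE), adjusted p = 0.049). Leaving out any library other than phosphoramidon replicate 3 ended the MME call (log2 fold change -0.35 to -0.28), and leaving out any other than untreated replicate 2 ended the PHEX call (0.33 to 0.46). ECE1 passed in all 6 such fits. With the replicate number as a block, the MME and PHEX calls were lost too. As a list the M13 genes did not pass camera (adjusted p = 0.57), with 2 members higher and 1 lower, also when adjusted over the list alone.

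EDN1 (ENSG00000078401, chromosome 6, 12290363 to 12297194), the precursor of the vasoconstrictor endothelin-1 and the gene whose product ECE1 processes, fell from 3.64 ± 0.447 to 1.02 ± 0.0510 FPKM (log2 fold change -1.80 ± 0.11 (SE), adjusted p = 2.0e-05). NPR1, a natriuretic peptide receptor, fell from 10.8 ± 0.281 to 6.54 ± 0.451 FPKM. Among the endothelin, natriuretic peptide, kinin and angiotensin genes, 2 of 12 tested members were higher and 5 lower (the same adjusted over the list alone). The list did not pass camera (adjusted p = 0.18), but did so without phosphoramidon replicate 1 (adjusted p = 0.03) or replicate 3 (adjusted p = 0.047), with the stricter filter (adjusted p = 0.019) and after thinning (adjusted p = 0.024). Over all alternatives its adjusted p ran from 0.0052 with fry to 0.53 with an estimated correlation. NPPB (0.79) and NPPC (1.43), natriuretic peptide precursors named after their values were seen, were the members that rose. Those that fell were EDN1, NPR1 and, named afterwards, AGT (-0.51), ADM (-0.30) and RAMP2 (-0.98).

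**Figure D1:**
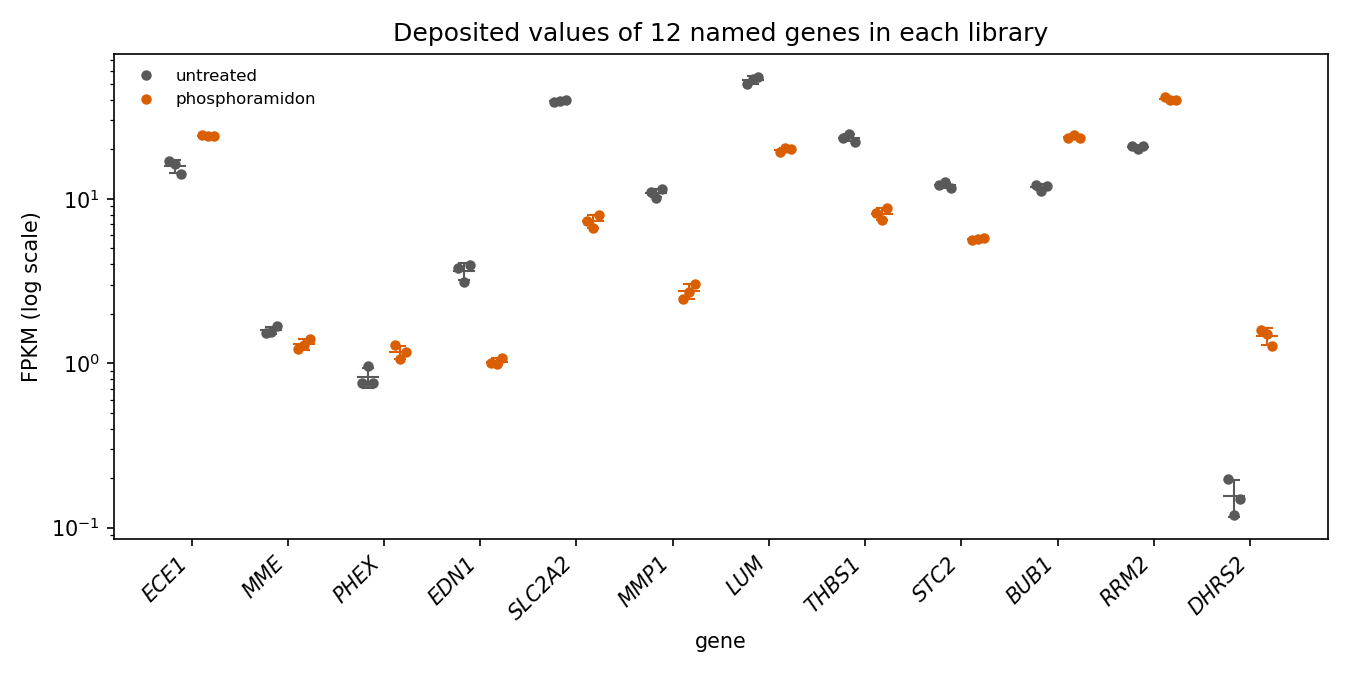
FPKM of 12 named genes on a log axis in each library of untreated (grey) and phosphoramidon-treated (orange) HK-2 cells, with dots for libraries, dashes for the mean and bars for the SD (n = 3). ECE1 lies at 15.8 and 24.2 FPKM on average, and SLC2A2 at 39.4 and 7.32.

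Beyond DHRS2, the 10 highest fold changes of the rule for named genes included those of the dysferlin-family pseudogene FER1L4 (1.33 ± 0.282 to 4.43 ± 0.231 FPKM), the chemokine CXCL16 (0.630 ± 0.177 to 2.08 ± 0.216 FPKM), the costimulatory ligand ICOSLG (0.115 ± 0.0226 to 0.517 ± 0.0694 FPKM) and the chemokine CCL20 (1.16 ± 0.221 to 3.18 ± 0.353 FPKM). QRICH2, STOX1 and RASD1 had log2 fold changes of 1.42, 1.32 and 1.21, and IGFBPL1 rose from 0.451 ± 0.0870 to 1.24 ± 0.225 FPKM. Several of these genes lay below 1 FPKM in untreated cells, where the pseudocount lowers the fold change.

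Among called genes with a symbol, a mean of at least 50 fragments and no overlap between groups, the lowest fold changes were those of the small nuclear RNA pseudogene RNU1-70P (31.6 ± 3.34 to 5.52 ± 1.72 FPKM, log2 fold change -2.61) and SLC2A2 (log2 fold change -2.49 ± 0.06 (SE), adjusted p = 7.1e-07). RNU1-70P lies 1315 bp beyond the end of SLC2A2 on the same strand. GASK1B, MMP1 and the integrin subunit ITGB6 followed with -2.24, -2.02 and -1.89. INHBA and INHBE, which encode activin subunits, fell from 1.65 ± 0.132 to 0.408 ± 0.103 FPKM and from 7.46 ± 0.293 to 2.18 ± 0.236 FPKM. CCN5 and the formyl peptide receptor FPR1 had log2 fold changes of -1.76 and -1.74.

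Genes of mitosis rose together. In the G2/M list, 35 of 40 tested members were higher and 0 lower (39 and 0 adjusted over the list alone), with a median log2 fold change of 0.59. The spindle checkpoint kinase BUB1 rose from 11.8 ± 0.559 to 23.8 ± 0.692 FPKM, the chromokinesin KIF4A from 12.9 ± 0.286 to 23.7 ± 0.0608 FPKM, the mitotic kinesin KIF20A from 15.3 ± 0.286 to 26.6 ± 0.597 FPKM and the securin PTTG1 from 15.6 ± 0.499 to 25.6 ± 0.593 FPKM. For DNA replication, 23 of 45 tested members were higher and 2 lower (24 and 2 adjusted over the list alone), with a median of 0.19. The ribonucleotide reductase subunits RRM2 and RRM1 rose from 20.6 ± 0.532 to 40.6 ± 1.15 FPKM and from 27.3 ± 0.632 to 36.5 ± 1.02 FPKM, ORC6 of the origin recognition complex from 9.15 ± 0.135 to 13.7 ± 0.933 FPKM and the transcription factor E2F1 from 9.66 ± 0.539 to 15.4 ± 1.29 FPKM. MCM2 and MCM5, helicase subunits named after their values were seen, were the members that fell (-0.24 and -0.19). Both lists passed camera (adjusted p = 8.6e-18 and 2.6e-05). With an estimated correlation the mitosis list kept its call (adjusted p = 0.02) and the replication list lost it (adjusted p = 0.27).

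Ribosomal protein genes fell almost throughout. Of 72 tested, 70 were lower and 0 higher (71 and 0 adjusted over the list alone), with a median log2 fold change of -0.39 and a middle range from -0.44 to -0.33. The others were RPL38 (-0.22) and RPS10 (0.15 ± 0.16, SE), named after their values were seen. RPS10 was low, at 1.12 ± 0.186 against 1.32 ± 0.233 FPKM, where the list's median in untreated cells was 114 FPKM. RPL13A fell from 419 ± 23.5 to 279.6 ± 7.93 FPKM, RPL34 from 42.7 ± 1.503 to 29.4 ± 1.08 FPKM and RPS3A from 296 ± 1.004 to 223 ± 6.83 FPKM. For ribosome biogenesis and MYC targets, 1 of 36 tested members was higher and 23 lower (the same adjusted over the list alone). Those that fell included the nucleolar protein NPM1 (189.6 ± 3.72 to 158 ± 2.06 FPKM), the spermidine synthase SRM (-0.52), the coactivator PPRC1 (-0.50) and the mitochondrial transcription factor TFB2M (-0.35). ODC1, the ornithine decarboxylase, was the member that rose (0.25). MYC itself, named like ODC1 after its value was seen, had a log2 fold change of 0.01 ± 0.05 (SE). Camera gave adjusted p = 1.4e-21 for the ribosomal proteins and 2.6e-05 for ribosome biogenesis, and both calls were lost with an estimated correlation (adjusted p = 0.27 for each). Many ribosomal protein genes have processed pseudogenes, which together held 0.0154 to 0.0188% of the fragments per library.

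In the ATF4 and amino acid list, 2 of 40 tested members were higher and 31 lower (2 and 36 adjusted over the list alone), with a median of -0.37. The cystine transporter SLC7A11 fell from 5.65 ± 0.443 to 2.24 ± 0.217 FPKM, the glycoprotein STC2 from 12.1 ± 0.444 to 5.69 ± 0.0687 FPKM, the proline synthesis enzyme PYCR1 from 17.9 ± 0.413 to 8.64 ± 0.386 FPKM and the serine synthesis enzyme PSAT1 from 27.5 ± 0.509 to 17.7 ± 0.809 FPKM. The members that rose were the stress-induced factor ATF3 (0.64) and the sestrin SESN2 (0.24). ATF4 itself, named with SESN2 after its value was seen, fell by 0.51 on the log2 scale. The list passed camera (adjusted p = 3.3e-12) but not with an estimated correlation (adjusted p = 0.27).

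Among TGF-beta targets and matrix genes, 2 of 34 tested members were higher and 24 lower (2 and 26 adjusted over the list alone), with a median of -0.29. THBS1, which encodes thrombospondin 1, fell from 23.5 ± 1.17 to 8.12 ± 0.682 FPKM, the matrix glycoprotein TNC from 64.2 ± 3.52 to 30.4 ± 0.542 FPKM, the collagen crosslinker LOX from 13.9 ± 0.459 to 6.43 ± 0.271 FPKM and the collagen chain COL1A1 from 10.1 ± 0.676 to 4.12 ± 0.241 FPKM. Fibronectin, FN1, with a mean of 2505 FPKM in untreated cells, fell by 0.79 on the log2 scale. TGFB1 (0.16) and LTBP1 (0.56), named after their values were seen, rose. Among mesenchymal markers, 2 of 14 tested members were higher and 9 lower (the same adjusted over the list alone), and the intermediate filament gene VIM fell from 104 ± 3.48 to 81.8 ± 2.22 FPKM. Among fibroblast and mesangial markers, 1 of 9 tested members was higher and 6 lower (1 and 7 adjusted over the list alone), led by the proteoglycan LUM (53.04 ± 2.85 to 19.9 ± 0.553 FPKM) and by COL1A1, which the matrix list also holds. ACTA2, smooth muscle actin and a member of both of the latter lists, rose (0.57), as did the mesenchymal cadherin CDH2 (0.17). Both were named after their values were seen. Among metalloproteinases, ADAMs and TIMPs, 4 of 26 tested members were higher and 11 lower (5 and 11 adjusted over the list alone), and the matrilysin MMP7 fell from 35.0 ± 0.915 to 15.2 ± 0.826 FPKM. ADAM8 (0.68), ADAM15 (0.19), ADAMTS12 (0.14) and MMP15 (0.21), named after their values were seen, rose. Camera gave adjusted p = 1.9e-08 for matrix genes, 0.0016 for fibroblast markers, 0.014 for mesenchymal markers and 0.039 for the metalloproteinases. With an estimated correlation each had adjusted p = 0.27. The estimate lay below the preset for fibroblast markers (-0.063) and metalloproteinases (-0.014), so those losses are no sign of correlation among their members. The metalloproteinase call was also lost without untreated replicate 1 (adjusted p = 0.057) or without untreated replicate 3 (adjusted p = 0.073). It was lost as well with the GC and length trend removed (adjusted p = 0.052) and with the replicate block. Its adjusted p ran from 3.7e-04 with fry to 0.27 with an estimated correlation.

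Among tubular injury and dedifferentiation genes, 2 of 29 tested members were higher and 17 lower (3 and 17 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 1.5e-04, and adjusted p = 0.27 with an estimated correlation). The cadherin CDH6 fell from 59.0 ± 1.19 to 29.4 ± 0.894 FPKM and the keratin KRT19 from 203 ± 13.1 to 94.2 ± 5.51 FPKM. CLU (0.54) and CCN1 (0.38), named after their values were seen, rose. HAVCR1, the kidney injury marker KIM-1, likewise named afterwards, had a log2 fold change of 0.02 ± 0.05 (SE). Among squamous genes, 0 of 8 tested members were higher and 4 lower (0 and 5 adjusted over the list alone), with the keratin KRT80 at -0.49 and stratifin, SFN, at -0.77, besides KRT81 (-0.79) and DSC3 (-0.36), named after their values were seen. Among nuclear-encoded oxidative phosphorylation genes, 1 of 51 tested members was higher and 10 lower (1 and 9 adjusted over the list alone), with a median of -0.08, and COX4I1 of cytochrome c oxidase had a log2 fold change of -0.26. SDHD, named after its value was seen, rose (0.17). Both lists passed narrowly (adjusted p = 0.038 and 0.024), but not with an estimated correlation (adjusted p = 0.27 and 0.66). The squamous call was lost without phosphoramidon replicate 2 (adjusted p = 0.058), without a filter (0.053) and with the GC and length trend removed (0.0565), in a range from 0.0027 with fry to 0.27 with an estimated correlation. The oxidative phosphorylation call was lost without phosphoramidon replicate 2 (adjusted p = 0.11) or replicate 3 (0.057), with the values as deposited (0.15) and with the trend removed (0.0665), in a range from 4.6e-04 without a filter to 0.66 with an estimated correlation. Its median as deposited was -0.01.

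**Figure D2:**
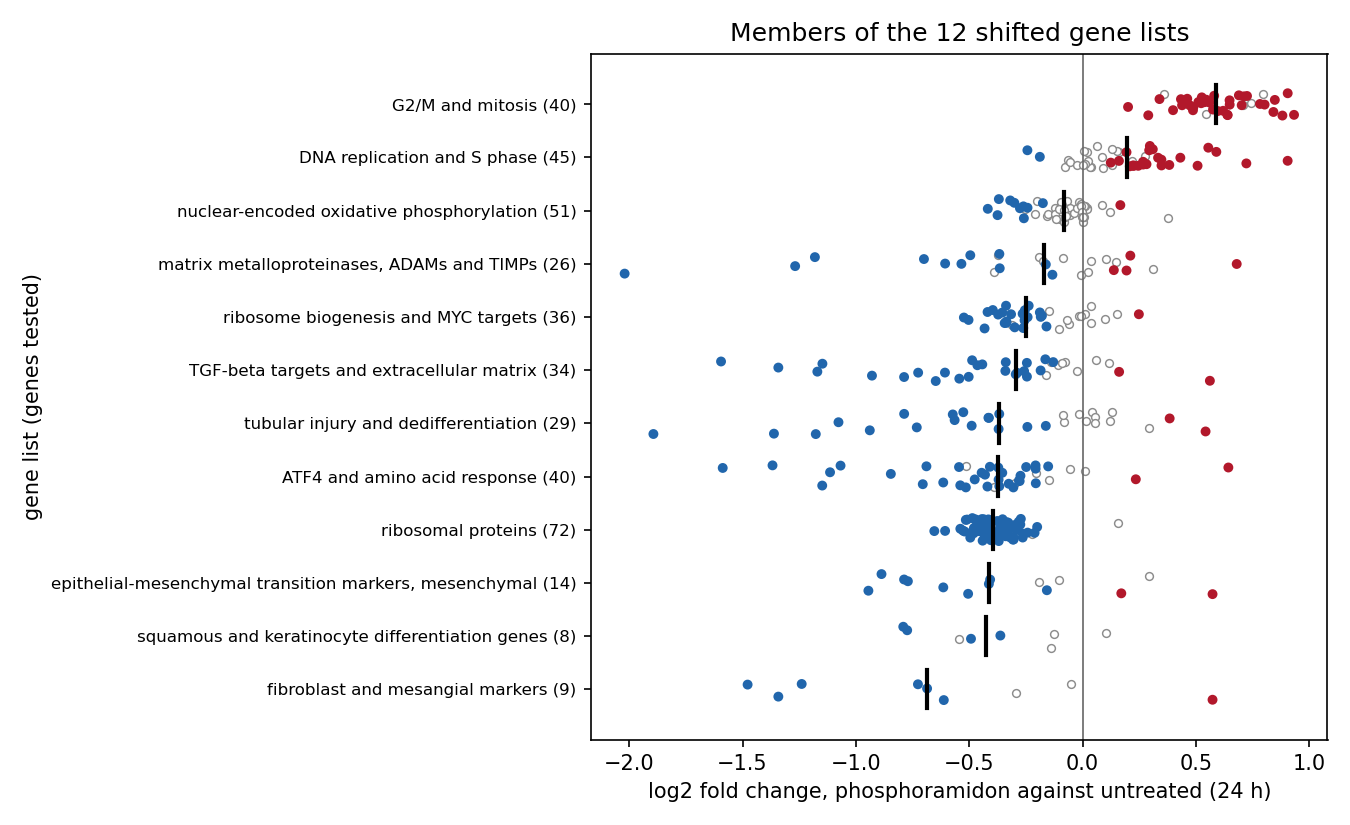
Log2 fold change (phosphoramidon against untreated) of every tested member of the 12 lists that passed camera, with filled dots for genes past the threshold (red higher, blue lower), open dots for the others and a black line at the median. The medians run from -0.69 for fibroblast and mesangial markers to 0.59 for G2/M and mitosis, and the former was -0.39 with a pseudocount of 1.

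The other tested lists did not pass camera at an adjusted p of 0.05, and 14 lists that did not pass it passed fry, the M13 and endothelin lists included. Since 33.6% of all tested genes were called, in both directions, counts near that share say nothing particular about a list. Values in parentheses after a gene are log2 fold changes, and each such gene passed limma's test. Where a count is 5 or lower, its members are named as far as they are reported, and those outside the rule were chosen after their values were seen. Single genes of nephron segments, junctions and the glomerulus fell, SCNN1A, SLC4A4, CLDN2 and TCF21 among them. Among 6 distal nephron markers tested, 1 was higher (AQP3) and 3 lower (SCNN1A, ATP6V0D2 and CLDN16), or 1 and 4 adjusted over the list alone. The sodium channel subunit SCNN1A (-1.12) and the proton pump subunit ATP6V0D2 (-1.14) had the lowest p-values, and the list had adjusted p = 0.056. ATP6V0D2 lay near the floor, at 0.303 ± 0.0631 to 0.0884 ± 0.0299 FPKM with a mean of 13.7 fragments. It passed the filter only through the untreated libraries, where it was higher. The bicarbonate cotransporter SLC4A4 (-0.76) and the inositol oxygenase MIOX (-0.98) had the lowest p-values of the proximal tubule identity genes, of which 3 of 20 were higher (PDZK1, KHK and GATM) and 7 lower, or 4 and 7 adjusted over the list alone. Proximal tubule identity had adjusted p = 0.21 as a list. The podocyte markers held 1 higher (PODXL) and 3 lower (TCF21, SYNPO and PLA2R1) of 5 tested, the same adjusted over the list alone, at an adjusted p of 0.3, led in p by the transcription factor TCF21 (-1.33) and podocalyxin, PODXL (1.13). Of 23 epithelial junction genes, 2 were past the threshold upwards (OCLN and CGN) and 6 downwards, the same adjusted over the list alone. Its adjusted p was 0.36, and the claudin CLDN2 (-1.12) and plakoglobin, JUP (-0.41) had the lowest p-values. The distal nephron markers passed without phosphoramidon replicate 3 (adjusted p = 0.037) and with the values as deposited (adjusted p = 0.022), in a range from 0.0014 with fry to 0.31 without a filter. Markers of endothelium had 0 called of 4 tested (adjusted p = 0.81), and too few leukocyte and erythroid markers were tested for a list test (2, of which 1, CSF1R, was lower).

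The fatty acid elongase ELOVL6, the sterol-responsive regulator INSIG1 and the uncoupling protein UCP2 fell, and carboxypeptidase D rose. Among 19 fatty acid synthesis genes tested, 3 were higher (ACSL3, GPAM and ELOVL5) and 8 lower, or 4 and 9 adjusted over the list alone. The fatty acid elongase ELOVL6 (-0.65) and the lipase PNPLA3 (-0.55) had the lowest p-values, and the list had adjusted p = 0.16. The sterol-responsive regulator INSIG1 (-0.49) was lower among the cholesterol synthesis genes, of which 3 of 26 were higher (SQLE, IDI1 and SC5D) and 9 lower, or 3 and 10 adjusted over the list alone. Cholesterol synthesis had adjusted p = 0.23 as a list. The fatty acid oxidation genes held 3 higher (ETFDH, ACADVL and CPT1A) and 10 lower of 31 tested, or 6 and 11 adjusted over the list alone, at an adjusted p of 0.41, led in p by the mitochondrial uncoupling protein UCP2 (-0.82) and the lipid droplet protein PLIN2 (-0.42). Of 35 lysosome and autophagy genes, 5 were past the threshold upwards (among them ATP6V1A, NEU1, LAMP2 and GLA) and 9 downwards, or 5 and 10 adjusted over the list alone. Its adjusted p was 0.52, and the glycoprotein GPNMB (-1.11) and the proton pump subunit ATP6V1A (0.36) had the lowest p-values. Among 14 cysteine and sulfide metabolism genes tested, 2 were higher (GOT1 and MAT2A) and 4 lower (CTH, MPST, SQOR and AHCY), or 2 and 5 adjusted over the list alone. The aspartate aminotransferase GOT1 (0.62) and cystathionine gamma-lyase, CTH (-0.85) had the lowest p-values, and the list had adjusted p = 0.81. Carboxypeptidase D, CPD (0.54) and carboxypeptidase M, CPM (-0.61) had the lowest p-values of the other peptidases, of which 5 of 24 were higher (CPD, TPP2, LNPEP, PRCP and IDE) and 4 lower (CPM, DPP7, DPP4 and ENPEP), or 6 and 4 adjusted over the list alone. Other peptidases had adjusted p = 0.78 as a list. The fatty acid synthesis list passed without a filter (adjusted p = 0.044, in a range from 0.0014 with fry to 0.46 with an estimated correlation). Of the 13 mitochondrially encoded genes 0 passed (also 0 adjusted over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 0.29).

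Signalling lists held members that changed in both directions, as did the tested genes as a whole. EREG and HBEGF, both EGFR ligands, went opposite ways, and the G1 cyclin CCND1 fell while the transcriptional repressor ID2 rose. Among 24 MAPK feedback and EGFR ligands tested, 5 were higher (HBEGF, TGFA, LRIG1, ERRFI1 and EGFR) and 10 lower, the same adjusted over the list alone. Epiregulin, EREG (-0.86) and heparin-binding EGF, HBEGF (0.72) had the lowest p-values, and the list had adjusted p = 0.18. The mRNA decay factor ZFP36 (-0.41) and the transcription factor ATF3 (0.64) had the lowest p-values of the immediate early genes, of which 6 of 27 were higher and 4 lower (ZFP36, FOSB, FOS and SRF), or 6 and 5 adjusted over the list alone. Immediate early genes had adjusted p = 0.57 as a list. The YAP targets held 8 higher and 7 lower of 22 tested, the same adjusted over the list alone, at an adjusted p of 0.99, led in p by the growth factor TGFB2 (-0.44) and the stress sensor GADD45A (0.50). Of 13 Wnt targets, 4 were past the threshold upwards (LGR4, NOTUM, ZNRF3 and LEF1) and 4 downwards (DKK3, CCND1, DKK1 and AXIN2), or 5 and 4 adjusted over the list alone. Its adjusted p was 0.57, and the dickkopf family member DKK3 (-0.87) and cyclin D1, CCND1 (-0.87) had the lowest p-values. Among 18 ID, BMP and Notch targets tested, 7 were higher and 6 lower, the same adjusted over the list alone. The Notch ligand JAG1 (-1.10) and the transcriptional repressor ID2 (0.82) had the lowest p-values, and the list had adjusted p = 0.95.

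In the stress lists, the thioredoxin reductase TXNRD1 rose while SLC7A11 fell. Among 36 hypoxia targets tested, 14 were higher and 9 lower, or 16 and 9 adjusted over the list alone. STC2 (-1.15) and LOX (-1.17) had the lowest p-values, and the list had adjusted p = 0.31. The translesion polymerase POLH (0.56) and the ribonucleotide reductase subunit RRM2B (0.58) had the lowest p-values of the p53 targets, of which 8 of 27 were higher and 5 lower (PLK2, PHLDA3, GDF15, MDM2 and AEN), or 8 and 6 adjusted over the list alone. p53 targets had adjusted p = 0.52 as a list. The apoptosis regulators held 6 higher and 3 lower (BID, XIAP and CASP8) of 21 tested, or 7 and 3 adjusted over the list alone, at an adjusted p of 0.53, led in p by the survival gene BCL2L1 (0.36) and the death agonist BID (-0.40). Of 28 NRF2 targets, 8 were past the threshold upwards and 11 downwards, or 11 and 11 adjusted over the list alone. Its adjusted p was 0.68, and the thioredoxin reductase TXNRD1 (0.73) and SLC7A11 (-1.37) had the lowest p-values. Among 24 heat shock genes tested, 5 were higher (HSPA1B, HSPA4L, HSPA1A, HSP90AA1 and DNAJB1) and 3 lower (SERPINH1, HSPA4 and HSPB1), the same adjusted over the list alone. The chaperone HSPA1B (0.82) and the collagen chaperone SERPINH1 (-0.60) had the lowest p-values, and the list had adjusted p = 0.7. The ERAD component SEL1L (0.40) and the COPII component SEC24D (-0.45) had the lowest p-values of the unfolded protein response genes, of which 6 of 26 were higher and 5 lower (SEC24D, HERPUD1, XBP1, OSTC and SEC61B), the same adjusted over the list alone. Unfolded protein response had adjusted p = 0.95 as a list. The metallothioneins held 0 higher and 3 lower (MT1A, MT1M and MT1F) of 11 tested, the same adjusted over the list alone, at an adjusted p of 0.56, led in p by MT1A (-0.96) and MT1M (-0.61). Of 9 aryl hydrocarbon receptor targets, 0 were past the threshold upwards and 3 downwards (SLC7A5, CYP1A2 and TIPARP), or 1 and 3 adjusted over the list alone. Its adjusted p was 0.41, and the amino acid transporter SLC7A5 (-0.42) and the cytochrome CYP1A2 (-0.96) had the lowest p-values. HSPA1A, HSPA1B and the metallothioneins have near-identical copies, so their values are uncertain. CYP1A2 lay near the floor, at 0.167 ± 0.0117 to 0.0422 ± 0.0310 FPKM with a mean of 7.83 fragments. It passed the filter only through the untreated libraries, where it was higher, and its call was lost without a filter.

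Of inflammatory genes, the chemokine CXCL8 and the complement component C3 fell, while the chemokine CCL20 (1.32) rose. More members of their list rose than fell. Among 30 NF-kappaB and cytokine genes tested, 12 were higher and 7 lower, or 12 and 10 adjusted over the list alone. Interleukin-8, CXCL8 (-0.63) and the complement component C3 (-0.74) had the lowest p-values, and the list had adjusted p = 0.81. The GTPase GBP1 (-1.06) and IFI44L (-1.15) had the lowest p-values of the interferon-stimulated genes, of which 6 of 33 were higher and 5 lower (among them GBP1, IFI44L, RIGI and ISG15), or 7 and 5 adjusted over the list alone. Interferon-stimulated genes had adjusted p = 0.99 as a list. The antigen presentation genes held 3 higher (TAP1, PSMB9 and B2M) and 2 lower (PSMB8 and HLA-B) of 14 tested, the same adjusted over the list alone, at an adjusted p of 0.78, led in p by the peptide transporter TAP1 (0.43) and the immunoproteasome subunit PSMB9 (0.32). Of 14 replication-dependent histones, 2 were past the threshold upwards (H2BC4 and H2AC11) and 3 downwards (H1-2, H2AC6 and H4C8), or 3 and 4 adjusted over the list alone. Its adjusted p was 0.94, and H1-2 (-0.48) and H2AC6 (-0.27) had the lowest p-values. The test and the median differed in sign for the metallothionein, antigen presentation, cysteine, unfolded protein and YAP lists, whose medians lay near 0. For the unfolded protein and interferon lists the test differed in sign from the mean. Of the 109 named genes, 27 overlap another tested gene, among them GASK1B, ITGB6, TAP1 and PSMB9, and without stated use of strand their reads cannot be fully told apart.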

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

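Alternatives chosen after seeing the data were no scaling, pseudocounts 0.01 and 1, the GC and length correction and thinning, as well as voom, upper-quartile factors and the stricter filter for the 1.5-fold count and voom, upper-quartile factors and no filter for the lists. Of the planned tests, limma-voom was run on the recovered fragments. The quasi-likelihood and Wald tests were not run, although these fragments could have served for them. No named gene or list reversed. The count of 5431 changed genes stayed within 1.5 times under every alternative except no filter, which tested 34618 genes and called 3544, of which 1378 were higher. Leaving out 1 library gave 4046 to 4818. The count of 130 genes past 1.5-fold became 273 with voom (69 higher and 204 lower), 70 without a filter (13 and 57), 68 with pseudocount 1 (11 and 57), 1106 at a tested fold of 1.2 and 16 at 2. Without 1 library it was 85 to 137, lowest without untreated replicate 2, with 13 to 22 higher and 68 to 115 lower. The 12 lists became 1 with an estimated correlation and 26 with fry, which asks another question, and 10 to 13 without 1 library. A call lost with an estimated correlation does not by itself show correlated members. For the fibroblast, metalloproteinase and squamous lists the estimates (-0.063, -0.014 and -0.012) lay below the preset 0.01. Removing the GC and length trend left 9. The causes were not tested, beyond the tested folds and the larger number of genes tested without a filter.

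The labels give both groups the numbers 1 to 3, but same-numbered libraries did not deviate together (correlations 0.11, -0.02 and -0.01 across genes, where each had to exceed 0.1), and not every library correlated best with its own number. With the replicate block, 5454 genes, 126 genes past 1.5-fold and 11 lists were called, without the metalloproteinase list and without MME and PHEX among named genes. Of the 109 named genes, 106 kept their side of the threshold under every alternative that tested them and 107 under each fit without 1 library that tested them. The exceptions were MME, PHEX and, without a filter, CYP1A2. ATP6V0D2 and CYP1A2 fell below the minimum without any 1 untreated library and with the stricter filter, and CYP1A2 also after thinning. Depth limits genes near 10 fragments: 1 fragment at 1 kb is 0.0401 to 0.0535 FPKM.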

Other observations

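Gene families were also grouped by the letters that open their symbols, a grouping chosen after the data were seen. The RPL, RPS, kinesin and keratin families share called members with the lists above, so their results partly repeat those of the lists. Of 163 families with at least 10 tested protein-coding genes, 9 passed camera, RPL and RPS among them, at a preset correlation of 0.01 and none with an estimated correlation (adjusted p = 0.9). Among centrosomal CEP genes, 17 of 38 were higher and 1 lower (adjusted p = 3.2e-05). Kinesins (KIF) had 17 of 33 higher and 5 lower (adjusted p = 0.014), and nucleoporins (NUP) 8 of 22 higher and 0 lower (adjusted p = 0.0072). Of mitochondrial ribosomal protein genes, 23 of 48 MRPL genes (adjusted p = 1.3e-04) and 10 of 29 MRPS genes (adjusted p = 0.014) were lower and 0 higher in either. Of 13 keratins 7 were lower and 0 higher (adjusted p = 9.0e-04), and of 12 EEF genes, which include translation elongation factors, 7 were lower and 1 higher (adjusted p = 0.014). No chromosome passed, the lowest of 24 adjusted p-values being 0.49.

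A pair of loci on chromosome 21 with no symbol, annotated as lincRNA, took many fragments. Both were much lower in phosphoramidon libraries and varied widely between replicates. ENSG00000280614 (8393419 to 8394341) had 287 ± 117 against 58.0 ± 36.0 FPKM (SD, n = 3, limma adjusted p = 0.015), and ENSG00000281181 (8437629 to 8438551) had 458 ± 162 against 112 ± 42.8 FPKM (adjusted p = 0.015). Both were chosen after their values were seen. The source of their reads was not tested, so their fall is not taken as a response of lincRNA genes.

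The tests for RNU1-70P and the splits were chosen after the results were seen. The others were written down before the values they measure, when a weak trend of fold change on GC content, the library shares of ribosomal protein genes and the fall of ENSG00000276980 were already known. The first pattern is the lower ribosomal protein genes. After the trend of each library on GC content and transcript length was removed, the list's median log2 fold change was -0.377 (-0.39 before), and after thinning every library to the lowest depth it was -0.395, with the list past the threshold both times. Among counted fragments, pseudogenes of these genes took up none of the loss: their share changed by -0.258% of it (SE 0.124). How reads that match several places were treated is not known. Reads left out of the counts would show in neither genes nor pseudogenes. These values argue against the GC and length trend and against pseudogenes as the whole cause, for pseudogenes among counted fragments alone. Thinning cannot decide on depth: it leaves the expected share of each gene unchanged, so the median of a well-covered list could hardly move. A response to phosphoramidon stays open as a hypothesis, as does any other difference between the cultures of the groups, which was not tested.

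The higher mitosis genes were tested in the same way. Their median was 0.581 after removal of the GC and length trend and 0.582 after thinning (0.59 before), with the call kept both times. The first value argues against the GC and length trend as the whole cause. Thinning cannot decide on depth here either, for the reason given above. A response to phosphoramidon stays open as a hypothesis, as does any other difference between the cultures of the groups, and neither was tested.

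The last pattern is a pair of lower non-coding loci. RNU1-70P may be read from transcripts that run on from SLC2A2, which stays open: the log2 ratio of RNU1-70P to SLC2A2 fragments differed between groups by -0.128 (SE 0.319), but both fold changes had prompted the idea, so this is no independent support. Reads shared with other U1 copies stay open too: the median over tested copies first planned could not be taken, since none of the other 52 reached the minimum, and their sum, a test set up once this was known, had a log2 ratio of 0.403 (SE 0.285) on values near the floor. For ENSG00000276980, which lies inside C3 (chromosome 19, 6716386 to 6717742), intron-keeping C3 transcripts were the explanation put forward, but its log2 ratio to C3 differed between groups by -1.55 (SE 0.188), so it fell further than C3, which argues against C3 transcripts at a fixed share of intron as the whole cause.

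The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave 5431 genes, and the highest of the other splits gave 0. It was also the only split (1 of 10) with 130 genes past 1.5-fold, again with 0 as the highest other. For lists, the real split gave 12 and was the highest (1 of 10), while the highest of the others gave 8. Each of the others sets 2 libraries of one group and 1 of the other against the reverse, which leaves part of the difference between groups in the comparison and puts the rest into the spread, so their counts are no measure of what unchanged libraries would give.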
